A study of Macaca fascicularis with 52 samples.

How the data were processed

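RNA was measured in 52 brain samples from 13 cynomolgus macaques (Macaca fascicularis) that had undergone a transient occlusion of the middle cerebral artery and had been randomly allocated to cyclosporine A (CsA) or placebo, per the series' design text. Each animal gave 4 samples, from the lesion, from the tissue around it (peri-lesion), and from the contralateral area that mirrors each of them. Tissue was taken on day 30, and the sites were located on FLAIR magnetic resonance images from day 7. Treatment, side, zone and animal were taken from the labels of each sample, which placed 6 animals in the CsA group and 7 in the placebo group. The labels also give a batch. Batch A holds 5 animals (2 CsA, 3 placebo) and batch B holds 8 (4 CsA, 4 placebo). The batch label and the label for the breeding of the animals are identical, so the batch and the breeding cannot be told apart.

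Directional mRNA libraries were made with a NextFlex Rapid kit (version 2.0) and sequenced as single-end reads of 75 bases on an Illumina NextSeq 500 (control software 4.0.1, base caller 2.4.11), per the series' design text. The reads were demultiplexed with bcl2fastq 2.17.1.14 and trimmed with cutadapt 1.9.1, per the submitters' processing notes. Trimming used a quality threshold of 30, a minimum length of 50 bases, at most 30% undetermined bases, and an adapter overlap of 3 bases with an error rate of up to 10%, per the series' design text. Reads were quantified with Salmon 1.6.0 against Ensembl release 106 of Macaca fascicularis, per the same text. The submitters' processing notes also name DESeq2, without a version.

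The authors deposited a table of estimated counts per gene, already in whole numbers, with 1 column per library. How transcript estimates were summed per gene is not given in the sources used here. The authors also deposited a normalized signal table, described there as corrected. Each value in it equalled the estimated count of the same gene and library times 1 factor per library, with a largest relative deviation of 5.3e-15 within a library. That factor was the inverse of the DESeq2 median-ratio size factor computed from the 14649 genes with a count in every library, and ran from 0.665 to 1.64. The deposited signal values therefore held no batch adjustment beyond this factor. The number of per-sample columns not used was 0.

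The tables listed 38343 genes, of which 9090 had no count in any library. The total estimated count per library ran from 15.9 M to 32.6 M, with a median of 23.1 M. A CPM value is the count per M counts of the library's effective total. That is its total times a scaling factor (TMM, described below), which ran from 0.636 to 1.45. At the median total and a factor of 1, 1 CPM stands for 23.1 counts. The labels name no molecular identifiers, so reads copied from the same molecule are not told apart and counting error covers only part of the error. The highest correlation of log2 CPM between any 2 libraries was 0.986, and no 2 libraries held identical values.

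Genes are named by Ensembl identifiers with a version. The files do not pair these with gene symbols, and 0 of the 40596 genes in the reference table used here carried an Ensembl identifier. The 380 entries of the 32 lists of pathway, cell type and drug target genes set up before the data were examined therefore had 0 members with a value, and their tests were void. For the same reason the naming rule was applied without its requirement of a symbol. That rule took the higher and lower genes with the largest log2 change among those with an adjusted p under 0.05, a mean of at least 2 log2 CPM, and the same sign in at least 12 of the 13 animals. It admitted 21 higher genes and 1 lower gene, and the text prints 2 identifiers that rose and 2 that fell. The lower identifier outside the rule, ENSMFAG00000035333.2, was chosen after its values were seen.

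Tests used the estimated counts with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed with filterByExpr at its default settings, libraries were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood F test was applied with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons within animals used all 52 libraries and 17239 genes, with the animal as a block and a separate effect of each site in CsA and placebo animals, which left 33 residual degrees of freedom. The effect over all 13 animals was the mean of the effects in both treatment groups. Comparisons of CsA with placebo at a single site used the 13 libraries of that site with the batch as a covariate. The lesion effect in batch B minus that in batch A was tested with the animal as a block. These tests, their samples and the alternatives to them were chosen before the data were examined, except where the text says otherwise. Fold changes are log2 values from edgeR. Log2 CPM values used a prior count of 2, and the deposited signal values were tested with limma 3.58.1 on log2 of the value plus 1.

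Principal components were computed from log2 CPM of 15897 genes. An injury score, devised after the data were seen, was the mean log2 CPM difference between the lesion and its mirror area in an animal, over the 200 genes that rose with the smallest p in the other animals. The same genes gave a score for the peri-lesion. Group differences in scores, components and library measures were tested two-sided by exact permutation over all 1716 splits of the 13 animals, and differences within animals by exact sign flips. The score's genes were not chosen again for each flip. Sign-flip p values of lesion scores are therefore not exact and may be too small. With 7 and 6 animals the smallest p that sign flips can give is 0.0156 and 0.0312.

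Samples of the same animal were paired by the label that names the animal. After the means of the site and treatment groups were removed, libraries of the same animal correlated with a mean Pearson r of 0.255 over gene-wise deviations, against -0.0176 for libraries of different animals. The consensus correlation of an animal's libraries was 0.196 with limma's duplicateCorrelation.

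The tests were checked on simulated counts drawn from the means, library sizes and dispersion trend of these libraries, with 100 genes changed by each fold. The changed genes had an average above 1 log2 CPM. Genes were drawn independently, each with the dispersion of the trend at its level, the same in every library. The shares below therefore do not cover genes that vary together or genes more variable than others of their level. Nor do they cover a wider spread in placebo lesions, or genes at lower levels. They may be too favourable for these libraries. For the lesion against its mirror in 13 animals (17053 genes), edgeR recovered 65% of changes of 1 log2 unit and 99% of changes of 2, and called 7 unchanged genes. For the lesion against its mirror in the 6 CsA animals (17067 genes), it recovered 26% and 97%, and called 1 unchanged gene. For the difference between the lesion effects of CsA and placebo animals (17067 genes), it recovered 5% and 66%, and called 2 unchanged genes. For CsA against placebo in the lesion (15705 genes), it recovered 17% and 91%, and called 6 unchanged genes. DESeq2 called 15 to 31 unchanged genes in the same 4 simulations.

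The alternatives were the DESeq2 1.42.0 Wald test, median-ratio factors in edgeR, no filter on low counts, the authors' signal table with limma, each batch alone, each animal left out in turn, no animal block, the animal as a random effect (limma voom), a single site effect for both treatments, all 52 libraries in a single fit, no batch covariate, and voom with sample weights. Added after seeing the data were fits of the 26 libraries of a zone alone, the first principal component of the contralateral libraries as a covariate, a fit without the peri-lesion mirror library of placebo animal 638, all alternatives of the injury score, and the DESeq2 test on the genes that passed edgeR's filter. The last was added because DESeq2, run on all genes with a count, also called genes with mean counts near 0 and implausible changes. In the peri-lesion over 13 animals, 122 of its 129 calls had failed the filter, with a median mean count of 0.212 and a median absolute log2 change of 17.3. Exact tests and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.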

Results

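Brain tissue was sampled 30 days after a transient occlusion of the middle cerebral artery, a model of ischemic stroke with reperfusion, in 13 cynomolgus macaques. The animals had received either placebo (7 animals) or cyclosporine A (6 animals), an immunosuppressant that inhibits calcineurin through cyclophilin A and also binds mitochondrial cyclophilin D. Each animal contributed a sample from the lesion, a sample from the peri-lesional tissue, and a sample from the contralateral mirror of each, for 52 mRNA libraries in all. The total estimated count per library ran from 15.9 M to 32.6 M (median 23.1 M). It averaged 24.6 M ± 5.46 (SD, n = 7) in the placebo lesions and 20.4 M ± 1.23 (SD, n = 6) in the CsA lesions. The lesion mirrors of placebo and CsA animals averaged 25.2 M ± 1.57 and 24.7 M ± 2.42. The peri-lesions averaged 21.3 M ± 2.05 and 23.2 M ± 5.11, and their mirrors 21.6 M ± 2.30 and 25.6 M ± 1.19. The design asks how the lesion and the peri-lesion differ from contralateral tissue of the same animal, and whether these differences depend on the drug. Genes are given by Ensembl identifier, since the files do not pair identifiers with symbols.

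The 3 libraries farthest from 0 on the second principal component were lesions of placebo animals, while on the first it was the peri-lesion mirror of placebo animal 638 (-197), which also had the lowest mean rank correlation with the others (0.777). On the second principal component, which held 12.3% of the variance of log2 CPM over 15897 genes, the placebo lesions averaged -64.3 ± 61.4 (SD, n = 7) and the CsA lesions 7.67 ± 14.4 (SD, n = 6). The difference of 72.0 between CsA and placebo lesions had an exact permutation p of 0.0128 (two-sided, 1716 splits), which became 0.176 after Benjamini-Hochberg adjustment over 18 tests of components. It was 81.1 in batch A (exact p = 0.2) and 63.1 in batch B (exact p = 0.0286). Lesions minus mirrors averaged -38.3 on this component over all 13 animals (permutation p = 0.0195, adjusted p = 0.176), with 3 of 13 animals above 0. The first component held 49.0% of the variance and did not part lesions from mirrors, with a mean difference of -29.9 ± 69.9 (SD, n = 13; permutation p = 0.15).

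**Figure D1:**
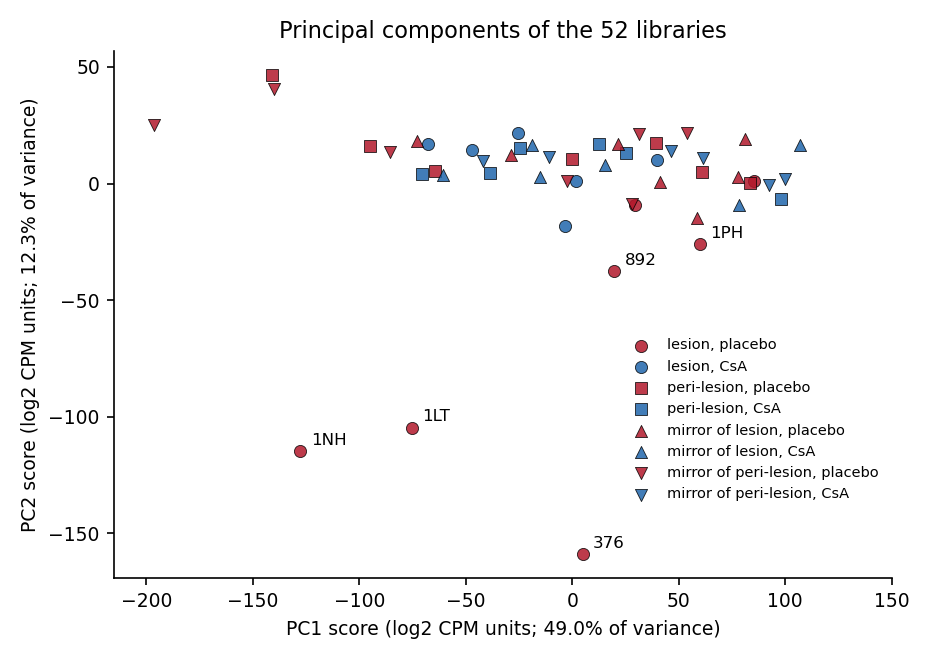
Principal component scores of the 52 libraries, in log2 CPM units, with PC1 on the x axis (49.0% of variance) and PC2 on the y axis (12.3%). Points are libraries, colours are treatments and shapes are sites; the labelled points are the 5 lesions of placebo animals that lie lowest on PC2, with 376, 1NH and 1LT farthest from 0 along PC2.

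In the lesion, 30 days after the occlusion, 549 genes were higher and 6 were lower than in the mirror area of the same animal, of 17239 tested over 13 animals (edgeR quasi-likelihood test, adjusted p under 0.05). The higher genes rose by a median of 1.35 log2 units (interquartile range 1.00 to 1.87), and the lower genes fell by a median of 0.67. ENSMFAG00000028880.2 rose by 2.31 log2 units (SE 0.33, edgeR adjusted p = 5.13e-05) and ENSMFAG00000000207.2 by 2.09 (SE 0.31, edgeR adjusted p = 0.000104). By log2 CPM each was higher in the lesion of 12 of 13 animals. Agreement in at least 12 was required by the rule that chose both identifiers and ENSMFAG00000043573.2. ENSMFAG00000043573.2 fell by 0.64 (SE 0.17, edgeR adjusted p = 0.0292) and was lower in the lesion of all 13 animals. Its fold stayed between -0.71 and -0.54 in 26 alternatives, but the adjusted p rose above 0.05 in 9, among them the fits without 1DY, 1LT, 376 or 635 (0.061 to 0.127). Its lesion level was 3.08 CPM ± 0.906 (SD, n = 7) against 4.53 ± 1.41 in the mirrors of placebo animals and 3.70 ± 1.64 (SD, n = 6) against 5.83 ± 1.30 in those of CsA animals. ENSMFAG00000035333.2, singled out after its values were seen because it had the smallest p among the 6 lower genes, fell by 0.62 (SE 0.15, edgeR adjusted p = 0.0135) and was lower in 9 of 13 animals. Its adjusted p rose above 0.05 in 7 of 26 alternatives, among them the fits without 1LT, 376 or 635 (0.0549 to 0.0819). The rise was uneven between animals, since 6 of the 549 higher genes were above the mirror in all 13 animals and 55 in at least 12. Of the 549 genes, 142 were under 1 CPM in the mirror areas, 297 from 1 to 10 CPM and 8 above 100 CPM, with the rest between. Over all 13 animals, 2259 genes had an unadjusted p under 0.05, against a mean of 862 from chance, around which correlated genes spread such counts widely. DESeq2 called 865 genes higher and 202 lower, or 833 and 42 on the genes that edgeR tested, a fit added after the data were seen. Voom with the animal as a random effect called 205 and limma on the deposited signal values 334. Fitted within a batch, edgeR called 1 gene in batch A (5 animals, 2163 at an unadjusted p under 0.05) and 3 in batch B (8 animals, 946). It called 2 genes when the lesion and mirror libraries alone were fitted, with 11 residual degrees of freedom in place of 33. There the 549 genes kept a median rise of 1.17 log2 units (median SE 0.33, against 0.30 in the main fit), and 548 had an unadjusted p under 0.05. The same libraries had given the calls, so these values are not independent of them. The count was 267, 297, 322, 328 or 338 without animal 376, 1LT, 1NH, 635 or 1NN.

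The calls were more numerous within the placebo group. In its 7 animals, 1550 genes were higher and 188 lower in the lesion than in its mirror by edgeR (lowest adjusted p = 2.13e-07). The higher genes rose by a median of 1.75 log2 units and 653 of them rose by more than 4-fold. The lower genes fell by a median of 0.59 log2 units. Of the 1550 higher genes, 547 were higher in all 7 animals and 1171 in at least 6. Of the 188 lower genes, 75 were lower in all 7 animals and 174 in at least 6. The 1550 genes held 7.59% ± 6.23 (SD, n = 7) of all counts in the placebo lesions, with a range of 1.65% to 15.7%, and 1.72% ± 0.294 in their mirrors. The 188 lower genes held 1.78% ± 0.459 in the lesions and 2.63% ± 0.701 in the mirrors. Higher genes came mostly from low levels, with 395 under 1 CPM in the mirror areas, 789 from 1 to 10 CPM, 348 from 10 to 100 CPM and 18 above. Of the lower genes, 106 lay from 10 to 100 CPM and 49 above. ENSMFAG00000028880.2 averaged 49.5 CPM ± 47.9 (SD, n = 7) in the placebo lesions and 3.14 ± 1.31 in their mirrors, and ENSMFAG00000000207.2 averaged 79.7 ± 65.4 and 5.53 ± 1.61. By edgeR these were rises of 3.74 log2 units (SE 0.47, adjusted p = 1.13e-06) and 3.64 (SE 0.45, adjusted p = 8.73e-07). ENSMFAG00000035333.2 fell by 1.00 log2 units (SE 0.21, edgeR adjusted p = 0.000995), from 160 CPM ± 58.2 (SD, n = 7) to 83.6 ± 45.1. The count of 1738 was 504 in batch A alone (3 placebo animals) and 305 in batch B alone (4 placebo animals), 753 with the lesion and mirror libraries alone (702 higher, 51 lower), and 3658 with a contralateral component as a covariate (2369 higher, 1289 lower). Without animal 376, 1LT or 1NH it was 770, 924 or 943.

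In the 6 CsA animals, no gene passed the edgeR test of the lesion against its mirror (lowest adjusted p = 0.929). An unadjusted p under 0.05 was found for 171 of 17239 genes, against a mean of 862 from chance. The median SE of a log2 change was 0.35 in this comparison. The fit gave each gene the same dispersion in placebo and CsA animals. Injury scores spread more widely in placebo lesions (SD 1.48, n = 7) than in CsA lesions (SD 0.45, n = 6). The SE may therefore be too large for CsA lesions, and the absence of calls does not show the absence of an effect. The 1550 genes that rose in placebo lesions had a median log2 change of 0.05 in CsA lesions, and their mean was above 0 in 3 of 6 animals (mean 0.06 ± 0.27, SD, n = 6; exact sign-flip p = 0.594). They held 2.06% ± 0.348 (SD, n = 6) of the counts in CsA lesions and 1.82% ± 0.396 in the mirrors. ENSMFAG00000028880.2 averaged 5.25 CPM ± 1.96 (SD, n = 6) in CsA lesions and 2.91 ± 0.97 in their mirrors, a log2 difference of 0.88 (SE 0.46, edgeR adjusted p = 0.929). Of the 6 animals, 5 lay above their mirror, and the rule that chose this identifier left no room for fewer. ENSMFAG00000000207.2 averaged 9.24 ± 6.05 and 6.0 ± 2.06, a log2 difference of 0.55 (SE 0.44, edgeR adjusted p = 0.929). The DESeq2 Wald test called 54 genes higher and 188 lower here (713 at an unadjusted p under 0.05), but 229 of these 242 failed the filter on low counts, with a median mean count of 0.288. On the genes edgeR tested, DESeq2 called 2 higher and 9 lower (273 at an unadjusted p under 0.05). Limma on the deposited signal values and voom with the animal as a random effect called 0 (239 and 142 at an unadjusted p under 0.05).

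**Figure D2:**
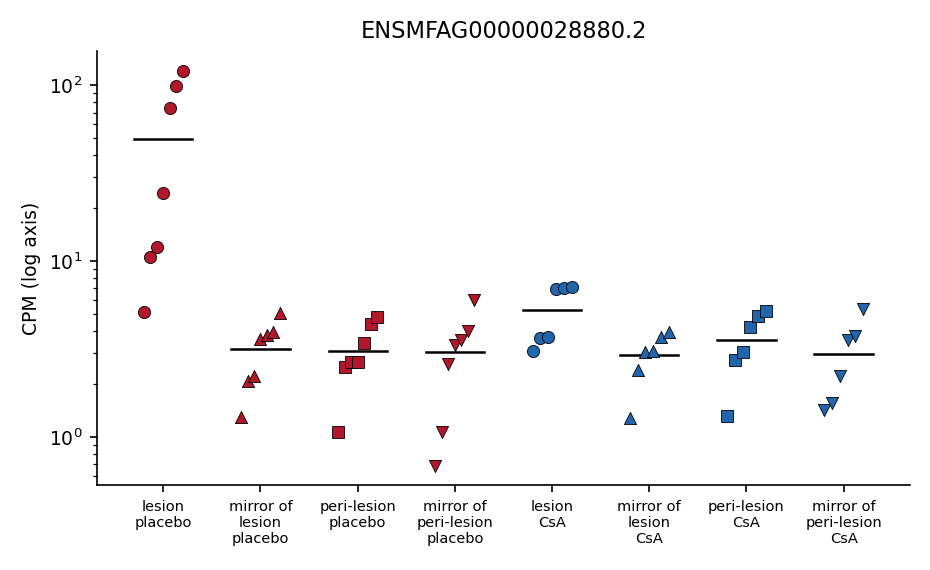
ENSMFAG00000028880.2 in every library, in CPM on a log axis, by site and treatment. Points are animals (7 placebo, 6 CsA) and horizontal lines are group means; placebo lesions average 49.5 CPM and CsA lesions 5.25 CPM, and both lie above their mirrors at 3.14 and 2.91 CPM.

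Tested directly, the lesion effect of CsA animals differed from that of placebo animals in 529 genes, of which 515 had a lower effect with CsA and 14 a higher effect (edgeR, lowest adjusted p = 0.000512; 2278 at an unadjusted p under 0.05). The 515 genes differed by a median of -2.31 log2 units (interquartile range -3.01 to -1.72). Their median lesion effect was 2.21 in placebo animals, with all 515 above 0, and -0.05 in CsA animals, with 230 above 0. The 14 genes had a median lesion effect of -0.68 in placebo animals and 0.37 in CsA animals. These medians come from the genes and libraries that gave the calls and are not independent of them. The CsA minus placebo difference was -2.86 log2 units for ENSMFAG00000028880.2 (SE 0.64, edgeR adjusted p = 0.0078) and -3.09 for ENSMFAG00000000207.2 (SE 0.61, edgeR adjusted p = 0.00411). For ENSMFAG00000035333.2 the difference was 0.77 (SE 0.30, edgeR adjusted p = 0.204) and for ENSMFAG00000043573.2 it was -0.20 (SE 0.34, edgeR adjusted p = 0.928). Within batch A and within batch B edgeR called 0 genes (814 and 1525 at an unadjusted p under 0.05, DESeq2 not run), and with the 26 lesion and mirror libraries alone it called 6 (2049). In that fit the 515 genes had a median difference of -2.03 (median SE 0.56, against 0.55 in the main fit). With a contralateral component as a covariate edgeR called 433 genes with a higher and 1308 with a lower effect, among them all 515. DESeq2 over all animals called 1214, and 1014 on the genes edgeR tested (93 higher, 921 lower), while voom with the animal as a random effect called 121 and limma on the deposited signal values 298. The count fell to 172, 218 or 275 without placebo animal 376, 1LT or 1NH, and to 244, 301, 247 or 251 without CsA animal 1DY, 639, 658 or 976.

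The injury score, which sums up the rise of lesion genes per animal, was 1.94 ± 1.48 log2 units (SD, n = 7) in placebo lesions and 0.203 ± 0.45 (SD, n = 6) in CsA lesions. The difference of -1.74 had an exact permutation p of 0.0233 (two-sided, 1716 splits), which became 0.0758 after Benjamini-Hochberg adjustment over 13 score tests. All 7 placebo scores were above 0 (exact sign-flip p = 0.0156, the smallest that 7 animals allow; adjusted p = 0.0677), and 3 of 6 CsA scores were (exact p = 0.344). Placebo animals 1LT, 376 and 1NH scored 3.47, 3.42 and 3.38, animals 1PH and 892 scored 1.56 and 1.37, and animals 653 and 638 scored 0.321 and 0.064. CsA animals ranged from -0.22 (1DY) to 0.849 (1NN), and 5 of 7 placebo animals lay above the highest CsA animal. In batch A the difference was -2.49 (2 CsA, 3 placebo; exact p = 0.2, where 10 splits cannot give less than 0.1), and in batch B it was -1.15 (4 and 4; exact p = 0.229). With the score's genes taken from animals of the other batch, the difference was -0.739 (exact permutation p = 0.255).

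**Figure D3:**
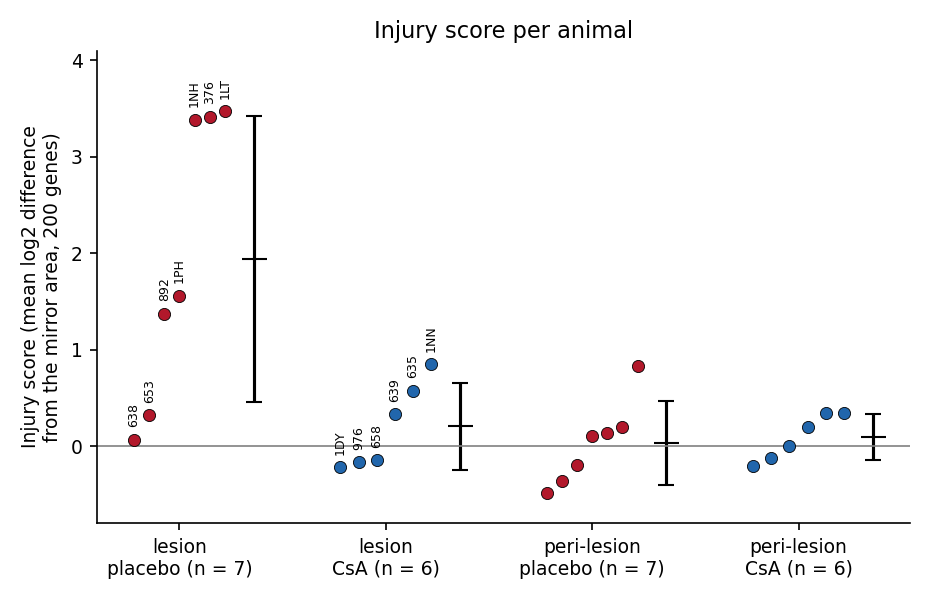
Injury score per animal, in log2 units over 200 genes (y axis), for the lesion and the peri-lesion of placebo and CsA animals (x axis). Points are animals, and the bar beside each group is the mean with 1 SD; placebo lesions range from 0.064 to 3.47, CsA lesions from -0.22 to 0.849, and no peri-lesion score exceeds 0.831.

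In the peri-lesion, no gene differed from the mirror area over the 13 animals by edgeR (152 of 17239 at an unadjusted p under 0.05, median SE 0.24), in the 7 placebo animals (78) or in the 6 CsA animals (1004). The 1550 genes that rose in the placebo lesions had a median log2 change of -0.02 in the placebo peri-lesion and 0.12 in the CsA peri-lesion. The 2 printed identifiers that rose in the lesion, ENSMFAG00000028880.2 and ENSMFAG00000000207.2, differed by 0.19 (SE 0.31) and 0.10 (SE 0.30) log2 units in the peri-lesion (edgeR adjusted p = 1 for each). The peri-lesion score averaged 0.0601 ± 0.348 (SD, n = 13; permutation p = 0.562), with 8 of 13 animals above 0, and differed by 0.0613 between CsA and placebo (exact permutation p = 0.774; -0.203 in batch A and 0.28 in batch B). The peri-lesion effect did not differ between CsA and placebo in any gene by edgeR (694 at an unadjusted p under 0.05). By DESeq2, 5 genes were higher and 124 lower in the peri-lesion over all animals (651 at an unadjusted p under 0.05), and 122 of these 129 failed the filter on low counts. It called 73 in placebo animals (618), 29 in CsA animals (1796) and 83 for the difference between the treatments (1563). On the genes edgeR tested, DESeq2 called 3 (240), 4 (143), 2 (1282) and 5 (1152) in these 4 comparisons.

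The lesion effect exceeded the peri-lesion effect in 17 genes over 13 animals and fell below it in none of the 17239 tested (edgeR, lowest adjusted p = 0.0328; 995 at an unadjusted p under 0.05; DESeq2 called 260 higher and 62 lower, or 154 and 7 of the genes edgeR tested). These 17 genes had a median change of 2.09 log2 units in the lesion and 0.10 in the peri-lesion. Both medians come from the genes and libraries that gave the calls and are not independent of them. ENSMFAG00000028880.2 differed by 2.12 log2 units (SE 0.44, edgeR adjusted p = 0.0444) and ENSMFAG00000000207.2 by 1.99 (SE 0.43, edgeR adjusted p = 0.0456). The injury score was 1.08 ± 1.35 higher in the lesion than in the peri-lesion (SD, n = 13; permutation p = 0.00293, adjusted p = 0.0381), in 10 of 13 animals. Its genes were chosen for a rise in the lesion of the other animals and not in the peri-lesion. That choice favours a higher score in the lesion, so the score is not separate evidence for the difference. The 2 contralateral areas did not differ in any gene by edgeR (229 at an unadjusted p under 0.05), and DESeq2 called 131 genes (855), or 5 of those edgeR tested (450). The count of 17 became 0 in each batch alone, without any of animals 1DY, 1LT, 1NN, 1PH, 376, 635, 639, 658 and 892, or without the peri-lesion mirror library of animal 638. It was also 0 with the animal as a random effect, with limma on the deposited signal values and with a single site effect for both treatments. It was 2 without 1NH, 5 without 976, 73 without 638, 122 without 653, and 29 without the animal block.

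**Figure D4:**
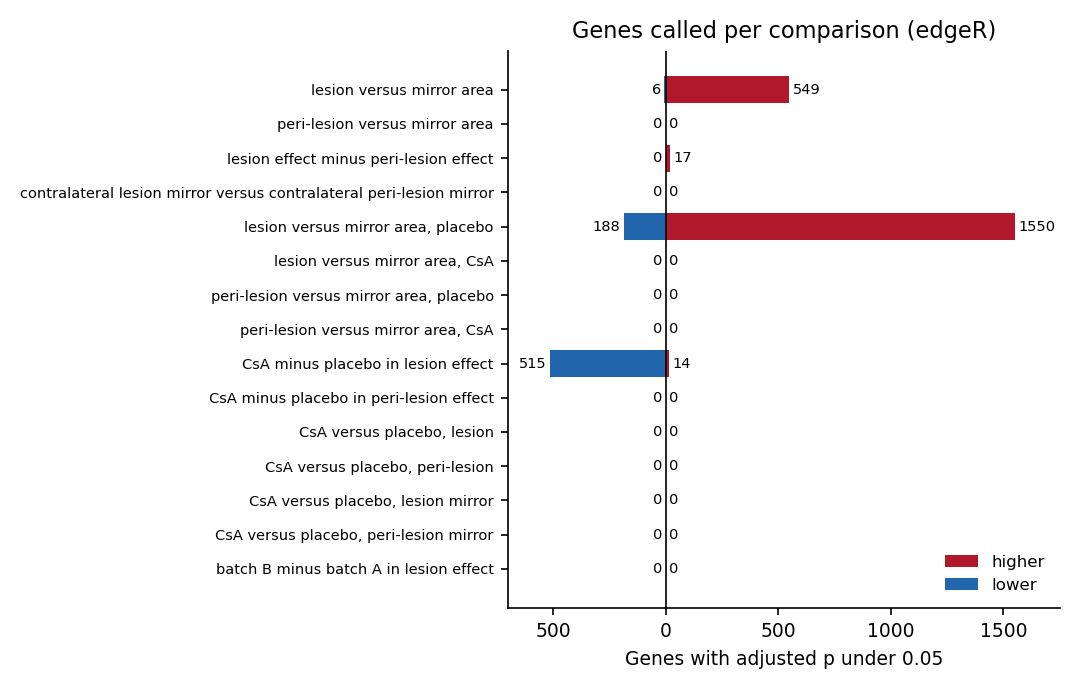
Genes with an edgeR adjusted p under 0.05 in each comparison (x axis, number of genes), with lower genes to the left of 0 and higher genes to the right. The placebo lesion has 1550 higher and 188 lower genes, the CsA lesion has 0, and CsA minus placebo in the lesion effect has 515 lower and 14 higher.

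Compared between animals at a single site, CsA and placebo lesions differed in no gene at an adjusted p under 0.05 by edgeR (lowest adjusted p = 0.0644). An unadjusted p under 0.05 was found for 3155 of 15840 genes, against a mean of 792 from chance. Genes that vary together spread such counts widely around the mean, so the excess alone is not evidence of a difference. Reassigned treatments called up to 2194 genes here at an edgeR adjusted p under 0.05. The log2 ratio of CsA to placebo lesions was -3.09 for ENSMFAG00000028880.2 (SE 0.67, edgeR adjusted p = 0.0644) and -2.99 for ENSMFAG00000000207.2 (SE 0.67, edgeR adjusted p = 0.0644). In the mirror of the lesion, the same identifiers differed by -0.09 (SE 0.34) and 0.13 (SE 0.26), with an edgeR adjusted p of 1 for each. No gene differed by edgeR in the peri-lesion (83 of 15686 at an unadjusted p under 0.05), the lesion mirror (306 of 15784) or the peri-lesion mirror (5128 of 15856, lowest adjusted p = 0.134). The count for the lesion was 1387 by DESeq2 (321 higher, 1066 lower), 1428 by DESeq2 on the genes that passed the filter, 1474 with all 52 libraries in a single fit, 372 without the filter on low counts and 152 without the batch covariate. It was 339 with voom and sample weights, 1196 with a contralateral component as a covariate, 461 without placebo animal 638 and 516 without placebo animal 653. DESeq2 called 0 genes in the peri-lesion and the lesion mirror (215 and 512 at an unadjusted p under 0.05, or 146 and 418 on the genes that passed the filter) and 2506 in the peri-lesion mirror (2671 with the filter), where voom with sample weights called 1.

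The lesion effect did not differ between the batches in any gene by edgeR (lowest adjusted p = 0.325; 2227 at an unadjusted p under 0.05), and DESeq2 called 321 genes, or 23 of those edgeR tested (3249 at an unadjusted p under 0.05). The scores were 2.81 ± 1.08 (SD, n = 3) and 1.29 ± 1.52 (n = 4) in placebo lesions of batches A and B, and 0.314 ± 0.756 (n = 2) and 0.147 ± 0.366 (n = 4) in CsA lesions. Of 18 exact tests of library totals, genes detected and the share of the 10 most abundant genes, none passed a Benjamini-Hochberg adjusted p of 0.05. The smallest p was for the total count of the peri-lesion mirror, 25.6 M ± 1.19 (SD, n = 6) in CsA against 21.6 M ± 2.30 (SD, n = 7) in placebo animals (exact p = 0.00408, adjusted p = 0.0734), with differences of 3.93 M in batch A (exact p = 0.3) and 4.32 M in batch B (exact p = 0.0286). CsA lesion libraries differed from placebo ones by -4.22 M (exact p = 0.101, adjusted p = 0.618), by -1.07 M in batch A (exact p = 0.8) and by -6.67 M in batch B (exact p = 0.0286).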

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

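Of the tests in this part, those of injury as a source of the first component, of a pooled spread, of batch, of depth, of the score genes and of composition for the lower lesion effect with CsA, and the 2 tests of exchanged tissue for the uneven lesion effect were chosen only after the result was seen, as was the injury score itself. Of these, 3 replaced an earlier test, and their bounds were set with the values in view. A pooled spread was first judged by the 6 genes called with the lesion and mirror libraries alone, which by its bound left that explanation open. The new test reversed the reading by its own bound, but cannot decide the question for the reason given below. The other 2 kept their first reading. They were composition (first the 1741 genes called with the covariate) and batch (first the smaller difference within a batch, -1.15). Depth was also examined by thinning every library to the lowest total, which is not used as a test because thinning leaves CPM the same on average.

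The lesion effect was lower with CsA than with placebo in 515 of the 529 genes in which the direct test of the difference passed, and the injury score differed by -1.74. With the score of any 1 animal left out, the unadjusted exact p of the score difference stayed at or under 0.0442 (highest without CsA animal 1DY). The genes that score the other animals were still chosen with that animal included, so its part in the gene choice was not removed. An uneven share of the batches does not account for the score difference. With the batches held apart it was -1.65 (exact p = 0.0286 over 700 splits within batches). Composition along the main contralateral component is argued against because all 515 genes stayed lower at an adjusted p under 0.05 with it as a covariate (median -2.23, against -2.31). With the 26 lesion and mirror libraries alone, the SE of the 515 genes was a median of 1.07 times as large. The median SE of all genes fell there from 0.48 to 0.417, and 6 genes were called on 11 residual degrees of freedom in place of 33. That fit still gave placebo lesions, CsA lesions and mirrors the same dispersion for each gene. It therefore cannot decide whether a pooled spread is too small for lesion libraries, or too large for those of CsA animals. A pooled spread and the part of a single animal in the gene choice therefore stay open. So does a set of score genes particular to a batch, since with genes from the other batch the score difference was -0.739 (exact p = 0.255). Depth also stays open, and was lower in the CsA lesions of batch B. Its relation to the score within treatments had too few animals (Spearman rho 0.17, 95% interval -0.42 to 0.659). Chance could not be excluded for the count, since 2 of 40 reassignments of the treatments within batches, the real one included, gave as many genes. The other called 557 after 635 and 653 exchanged treatments. Their scores were 0.575 and 0.321, so that split stayed close to the real one. With chance and these explanations open, a weaker lesion response with CsA is a hypothesis.

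The lesion effect was also uneven between animals, with scores of 3.47, 3.42 and 3.38 in placebo animals 1LT, 376 and 1NH and 0.321 and 0.064 in placebo animals 653 and 638. An exchange of lesion and peri-lesion tissue within an animal would put a peri-lesion score near 3.38, and the highest was 0.831. An exchange of lesion and mirror tissue would give a score far below 0, and the lowest was -0.22. Depth of the lesion library stays open, because the Spearman rho of the score with the total count was 0.258 (permutation p = 0.395) but its 95% interval reached 0.708, past the bound of 0.5 set beforehand (Pearson r = 0.56 in batch B, exact p = 0.135; -0.159 in placebo animals, exact p = 0.69). Differences in infarct size between animals may account for the spread, and stay untested because no size is given in the sources used here.

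The first component of the 52 libraries held 49.0% of the variance, and none of its 6 tests by site or treatment passed an adjusted p of 0.05. The share of its variance between animals was 0.315 (permutation p = 0.175, median share under permuted animals 0.230). Most of its variance therefore lay within animals, but a smaller part shared by all 4 libraries of an animal stays open. Over gene-wise deviations, both contralateral libraries of an animal correlated with a mean r of 0.517. The batches did not part on the animal means (difference -2.8, SD of the means 40.4, exact permutation p = 0.915). Injury alone is argued against because the contralateral libraries spread at least as widely, with a variance ratio of 1.36 over the ipsilateral ones. Sequencing depth stays open as a candidate source, since within animals the component followed the total count with a Spearman rho of 0.522 (permutation p = 0.00041; Pearson r = 0.501, permutation p = 0.00032, and 0.519 without the 2 farthest libraries; rho 0.648 in batch A and 0.408 in batch B), although over the 52 libraries it followed the TMM factor, computed from the same counts, with a rho of -0.986. A difference in tissue makeup between dissected pieces was not tested, because cell type markers had no values.

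The other comparisons were set against other splits of the same libraries. Only 1 of 40 exchanges of lesion and mirror within the 13 animals, the real split, gave 555 genes or more (highest other 486). That share of 0.025 is the smallest that 40 splits can give, and it was not corrected for the number of comparisons. It makes chance less likely for this count without excluding it. Chance could not be excluded for the 17 genes in which the lesion effect exceeded the peri-lesion effect (2 of 40 splits, highest other 82). The same held for the 1738 genes of the placebo lesion (2 of 40 splits, highest other 1772, after 638 and 653 exchanged sides). These were the placebo animals with the lowest scores, 0.064 and 0.321, so that split stayed close to the real one. Counts of 0 were matched by every split, which excludes nothing. This was 40 of 40 for the peri-lesion (highest other 7429) and the contralateral areas (0), and 32 of 32 for the CsA lesion (0). It was 40 of 40 for the placebo peri-lesion (6362), 32 of 32 for the CsA peri-lesion (1194), 40 of 40 for CsA minus placebo in the peri-lesion effect (0) and 40 of 40 for the batches (867). For CsA against placebo, 100 of 100 splits matched 0 in the lesion (highest other 2194), the peri-lesion (3909), the lesion mirror (5650) and the peri-lesion mirror (6410). Splits that call up to 7429 genes where the labelled one calls 0 point to a structure of the libraries. The 6362 came after 1NH and 1PH exchanged sides, the only placebo animals whose peri-lesion lay below its mirror on the first component. The 1194 came after 658 and 976 exchanged sides, the only CsA animals whose peri-lesion lay above its mirror there. These splits thus aligned the animals along that component. Whether it drives the counts was not tested.

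Single libraries stood apart from the rest of their group in 5 of 86 groups tested, where chance gives 4.3. CsA animal 639 had 18724 genes detected in the lesion mirror (19646 ± 181 in the other 5). The 10 most abundant genes of CsA animal 658 took 6.86% of the counts in the peri-lesion mirror (9.76% ± 0.394 in the other 5). Placebo animal 1PH lay at 46.7 on the second component in the peri-lesion (9.15 ± 6.82 in the other 6). ENSMFAG00000035333.2 stood at 289 CPM in the lesion mirror of placebo animal 1NH (138 ± 13.4 in the other 6), and ENSMFAG00000043573.2 at 11.2 CPM in the peri-lesion of CsA animal 976 (4.89 ± 0.871 in the other 5).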

How the results depend on the processing

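Of the values in this part, the fits of a single zone, the contralateral component as a covariate, the fit without the peri-lesion mirror library of animal 638, DESeq2 with the filter on low counts and all score alternatives were chosen after seeing the data. Of 367 counts of genes under an alternative, 282 stayed within 1.5 times and 85 did not. Of the 367, 266 belonged to the 11 results with a main count of 0, of which 237 stayed at 0. For the 4 results with calls, 45 stayed within 1.5 times and 56 did not. Of the log2 changes of the 4 printed identifiers, 82 kept their side of the threshold, 22 lost it and 0 changed sign. Of 19 score differences, all negative, 16 stayed under an exact p of 0.05 and 3 did not. The cause was not tested where a count moved, except where a setting leaves fewer libraries or genes. Depth limits the genes under 1 CPM, which stand on fewer than 23.1 counts at the median total and a TMM factor of 1.

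DESeq2 called 1067 genes in the lesion, 129 in the peri-lesion, 322 for lesion minus peri-lesion, 131 between the contralateral areas, 242 in the CsA lesion, and 73 and 29 in the placebo and CsA peri-lesion. It called 1214 for CsA minus placebo in the lesion effect and 83 in the peri-lesion effect, 1387 and 2506 for CsA against placebo in the lesion and the peri-lesion mirror, and 321 between batches. On the genes that passed the filter it called 875 in the lesion, 3 in the peri-lesion, 161 for lesion minus peri-lesion, 5 between the contralateral areas, 11 in the CsA lesion, and 4 and 2 in the placebo and CsA peri-lesion. There it called 1014 and 5 for CsA minus placebo in the lesion and peri-lesion effects, 1428 and 2671 for CsA against placebo in the lesion and the peri-lesion mirror, and 23 between batches. With the animal as a random effect, the lesion gave 205, lesion minus peri-lesion 0 and CsA minus placebo in the lesion effect 121, and limma on the deposited signal values gave 334, 0 and 298. Batch A alone gave 1 for the lesion, 0 for lesion minus peri-lesion, 504 for the placebo lesion and 0 for CsA minus placebo in the lesion effect. It also gave 1 and 3 for CsA against placebo in the lesion mirror and the peri-lesion mirror, and a score difference of -2.49. Batch B alone gave 3 for the lesion, 0 for lesion minus peri-lesion, 305 for the placebo lesion and 0 for CsA minus placebo in the lesion effect, and a score difference of -1.15. With score genes from the other batch the difference was -0.739.

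With the contralateral component as a covariate, the placebo lesion gave 3658 (1289 lower), CsA minus placebo in the lesion effect 1741 (433 higher) and CsA against placebo in the lesion 1196. CsA against placebo in the lesion was 1474 with all 52 libraries in a single fit, 152 without the batch covariate, 372 without the filter and 339 with sample weights, which also gave 1 in the peri-lesion and 1 in the peri-lesion mirror. The 26 libraries of the lesion zone alone gave 2 for the lesion, 753 for the placebo lesion and 6 for CsA minus placebo in the lesion effect. Lesion minus peri-lesion gave 0 with a single site effect for both treatments and 0 without the peri-lesion mirror library of 638. Without the animal block that names the pairing, lesion minus peri-lesion gave 29, and no other count moved by over 1.5 times. Leaving out each animal gave 267 to 799 for the lesion, 0 to 122 for lesion minus peri-lesion, 770 to 2178 for the placebo lesion, 172 to 785 for CsA minus placebo in the lesion effect and 0 to 516 for CsA against placebo in the lesion. Score differences ran from -2.05 to -1.48. The lesion count was lowest without 376 (267), 1LT (297), 1NH (322), 635 (328) and 1NN (338). The tests of the 32 preset gene lists with an estimated correlation were not run, because these lists had no members with a value.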

Other observations

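The comparisons in this part were chosen only after the results were seen. Across the 17239 genes tested, the lesion effects of placebo and CsA animals, which share no libraries, had a Pearson r of 0.101 and a Spearman rho of 0.203. Their peri-lesion effects had a Pearson r of -0.319 and a Spearman rho of -0.581. No gene passed edgeR in the peri-lesion of either group or in their difference. On the first component the peri-lesion averaged -16.6 against -44.5 in its mirror with placebo, and 0.295 against 41.2 with CsA. Whether these opposite shifts give the negative correlation was not tested. The r and rho values are correlations across genes, and genes are not independent replicates, so no p is given. The genes that rose in the placebo lesion held 1.80% ± 0.35 (SD, n = 7) of the counts in the placebo peri-lesion and 1.91% ± 0.332 (SD, n = 6) in the CsA peri-lesion, against 1.89% ± 0.412 and 1.64% ± 0.269 in their mirrors. The 188 genes that fell in the placebo lesion held 2.92% ± 0.361 (SD, n = 6) of the counts in CsA lesions and 2.67% ± 0.858 in their mirrors. Their median log2 change in the CsA lesion was 0.06, with 68.6% of them above 0 and 3 of 6 animals with a mean above 0 (exact sign-flip p = 0.375; a camera test with a preset correlation gave p = 0.00473, and p = 0.564 with an estimated correlation).

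The peri-lesion mirror, contralateral tissue away from the infarct, had 5128 of 15856 genes at an unadjusted p under 0.05 between CsA and placebo by edgeR (3155 in the lesion), with 0 at an adjusted p under 0.05 and 2506 called by DESeq2 (2671 on the genes that passed the filter on low counts). Its excess over the lesion did not hold throughout. The number at an unadjusted p was 2426 without placebo animal 638 (3380 in the lesion), 1070 with the contralateral component as a covariate (5163), 1441 in batch B alone (2954) and 3569 with sample weights (3776), against 1874 in batch A alone (819). On the first component of all libraries these samples averaged 41.2 ± 56.8 (SD, n = 6) with CsA and -44.5 ± 97.0 (SD, n = 7) with placebo, a difference of 85.7 (exact permutation p = 0.0897, adjusted p = 0.538 over 18 tests; 114 in batch A and 77.8 in batch B). The same libraries differed in depth by 4.08 M between CsA and placebo (exact p = 0.00408, adjusted p = 0.0734), and depth was not separated from treatment here.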
